A study of Mus musculus with 8 samples.

How the data were processed

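Total RNA of RAW264.7 cells was profiled 24 h after transfection with scrambled or Ypel5-specific siRNA, with 4 arrays per group. Per the labels, RNA was extracted on columns with DNase treatment, amplified to biotinylated cRNA and hybridised to Illumina bead arrays. Groups were taken from the source names and replicate numbers from the descriptions. The source names carry other numbers than the descriptions, so each was tried as a block.

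Per the file headers, the deposited non-normalized table gives for each of 25697 probes and 8 arrays an intensity on a linear scale and a detection p-value. The deposited detection p-value takes 101 levels on both arrays of replicate 1 and between 749 and 762 on the others. A second deposited table and the series' value table hold log2 intensities normalized by the authors. These log2 values are identical in both tables, and each column has a median of 7.636. Their sorted values lie within 0.0016 of the mean sorted log2 intensities of the non-normalized table, which is the pattern of quantile normalization without background subtraction. The submitters' processing notes name RMA, and no version is given in the sources used here. The deposited log2 values were used as alternatives beside quantile normalization without background correction. Counts of alternatives therefore hold nearly the same values more than once.

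Intensities were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, which infers the negative controls from the detection p-values, with an offset of 16 added before log2. The inferred background was 173 ± 5.52 in the scrambled and 189.9 ± 12.8 in the Ypel5 siRNA group (SD, n = 4 each, two-sided exact permutation p = 0.0857). Probes with a detection p under 0.05 on at least 4 of the 8 arrays, whatever their group, were kept (11364, or 44.2%). A gene was represented by its kept probe with the highest mean, which gave 8145 genes. Of the called genes 122 had several kept probes, 15 of them with a probe of opposite sign and 1 with such a probe at an unadjusted p under 0.05. Gene names came from the file and were updated through a RefSeq gene table (GRCm38.p6), used for names only. Of the probes, 20734 carried a current symbol, 3874 were renamed through a synonym and 127 through a gene identifier, and 962 kept the name in the file. No genome build is given in the sources used here, so no coordinates are printed. A probe below background on all arrays of 1 group gave only a bound on the fold, and 1 below background in both groups gave none.

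The groups were compared with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), without a replicate block. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 19 of 24 fixed lists with at least 3 measured genes, and again with an estimated correlation. The test fry was run beside it. It asks whether the genes of a list move on balance in 1 direction, without comparing them with other genes, and called 9 lists. With an estimated correlation camera called 0 lists, with 6 at an unadjusted p under 0.05. Among lists called at the preset, the estimate was above 0.01 for interferon-stimulated (0.213) and oxidative stress genes (0.020). It was below 0.01 for NF-kB (0.0098), oxidative phosphorylation (-0.014), glycolysis and hypoxia (-0.023) and macrophage identity genes (-0.034). Stronger correlation therefore does not account for the lost calls of the latter. Single values were compared by exact permutation of 4 against 4 arrays, for which the smallest possible two-sided p is 0.0286. The tests, the alternatives, the gene lists and the rule for naming genes were set before the data were examined, except where the text says otherwise. The rule names Ypel5; the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap; up to 4 members with the smallest p of each list described in detail; and Ifnb1, Tbk1, Ikbke, Irf3, Irf7, Tnf, Il6, Cxcl10, Ranbp9, Wdr26 and Ypel1 to Ypel4 whatever their values. Of the 12 largest falls 1 is not reported here.

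Background correction, normalization, the detection filter and the choice of probe were not tested by simulation. The limma fit was tested on simulated normalized values of the 8145 genes, with noise independent between genes. In these, 100 genes were changed by log2 0.5 and 100 by log2 1. The fit recovered 67% of the former and 94% of the latter, and 7 of its 168 calls (4.17%) were false. The alternatives changed the block, the background correction and its offset, the normalization, the detection filter, the treatment of several probes, the variance model and the arrays included. Leaving out both arrays of replicate 1 and testing gene families by symbol were added after the data had been seen.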

Results

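Gene expression was measured in RAW264.7 cells, a macrophage line derived from BALB/c mice. The cells had been transfected 24 h earlier with small interfering RNA (siRNA) against Ypel5 or with scrambled control siRNA. Each siRNA group had 4 Illumina bead arrays hybridised with biotin-labelled cRNA, and the titles place all 8 arrays on 1 chip. The labels number the replicates of each group but do not say that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Between 11249 and 11612 of the 25697 probes were detected per array, and the number of arrays limits the precision. The median intensity was 189 ± 6.26 in the scrambled group and 209.5 ± 14.6 in the Ypel5 siRNA group (SD, n = 4 each, two-sided exact permutation p = 0.0857, where the smallest possible is 0.0286). The study's title describes Ypel5 as a repressor of the kinases TBK1 and IKBKE and of interferon-beta, and the comparison addresses which transcripts differed after the Ypel5 siRNA.

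Ypel5 itself, read by the single probe ILMN_2951446, was detected on 0 of the 8 arrays. Its normalized log2 intensity was 4.70 ± 0.095 in the scrambled group and 4.79 ± 0.10 in the Ypel5 siRNA group (SD, n = 4 each, two-sided exact permutation p = 0.257). The difference of 0.09 (SE 0.08) had a limma adjusted p of 0.768 over all probes. Because both groups lay below background, no fold is given and the arrays could not show whether the siRNA lowered Ypel5 mRNA. The directions that follow are therefore those of the arrays labelled Ypel5 siRNA against those labelled scrambled.

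The largest rise after the Ypel5 siRNA was in Rsad2, which encodes the antiviral enzyme viperin. Its log2 intensity went from 7.67 ± 0.067 to 9.52 ± 0.077 (SD, n = 4 each), a 3.59-fold increase (log2 1.85, SE 0.058, limma adjusted p = 3.76e-06). Other interferon-inducible genes among the 12 largest rises were Cmpk2, a mitochondrial nucleotide kinase (log2 1.11, SE 0.15, adjusted p = 0.00795), Ifi44l (log2 1.07), Ifi202b (log2 1.06) and Ifit3 (log2 1.02, SE 0.076, adjusted p = 0.00104). The myeloid receptor genes Trem3 (log2 1.16, SE 0.12, adjusted p = 0.00294), Slamf9 (log2 1.16, SE 0.11, adjusted p = 0.00247) and Sirpb1a (log2 1.08) rose as well. Slpi, an inhibitor of leukocyte serine proteases, rose by log2 1.37 and the lysosomal transporter gene Slc46a3 by log2 1.24, each with 3 of the 4 scrambled arrays detecting its probe. Pdlim4, which encodes an actin-associated PDZ and LIM protein, was not above background on any scrambled array and was at least 1.83-fold higher in the Ypel5 siRNA group (adjusted p = 0.000350). The transcript given as ENSMUSG00000053338 was likewise at least 1.41-fold higher (adjusted p = 0.00247). These bounds set the mean of the brighter group against the lowest detected signal of each dimmer array, or the probe's own signal where that was higher. Without background correction the rises were smaller, at log2 0.51 for Slpi, 0.43 for Slc46a3, 0.52 for Slamf9 and 0.36 for Sirpb1a against 1.28 for Rsad2, so the sizes and order depended on it. Ifi202b and Sirpb1a belong to families of closely related genes, so their probes may also read relatives.

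The largest falls were smaller, and their order depended on background correction. Tmem41b, which encodes a lipid scramblase of the endoplasmic reticulum, fell by 0.88 on the log2 scale, from 7.04 ± 0.074 to 6.16 ± 0.34 (SD, n = 4 each, adjusted p = 0.0182). Diablo, a mitochondrial antagonist of inhibitor-of-apoptosis proteins, fell by 0.71 (SE 0.060, adjusted p = 0.00178). Socs5, a suppressor of cytokine signalling, fell by 0.57 (SE 0.054, adjusted p = 0.00247), the transcription factor gene Lyl1 by 0.58 (SE 0.057, adjusted p = 0.00290) and Rrm2b, a subunit of ribonucleotide reductase, by 0.58 (SE 0.082, adjusted p = 0.00874). Further falls were those of Hmga2 (log2 -0.84), Slc25a23 (log2 -0.65), Zfp871 (log2 -0.63), Slc41a2 (log2 -0.62), Acot2 (log2 -0.60) and Ehmt1 (log2 -0.56), with adjusted p between 0.0115 and 0.0465. Without background correction Diablo (log2 -0.64), Socs5 (log2 -0.45), Lyl1 (log2 -0.43) and Rrm2b (log2 -0.40) fell more than Tmem41b (log2 -0.32), Hmga2 (log2 -0.25) and Slc25a23 (log2 -0.20), and Ehmt1 and Acot2 (log2 -0.16 each) did not pass. In the Ypel5 siRNA group the probe was detected on 1 of 4 arrays for Acot2, on 2 of 4 for Hmga2 and on 3 of 4 for Slc25a23 and Ehmt1. Of the 12 falls, 4 (Diablo, Socs5, Lyl1 and Rrm2b) were past the threshold under every alternative that gave them a value, against 10 of the 12 rises. Leaving out 1 array ended the call of Tmem41b (scrambled replicate 1, adjusted p = 0.0514), and it did so for 5 of the 8 arrays with Zfp871, 6 with Ehmt1 and 7 with Hmga2, Slc41a2 and Acot2, where adjusted p reached 0.110.

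**Figure D1:**
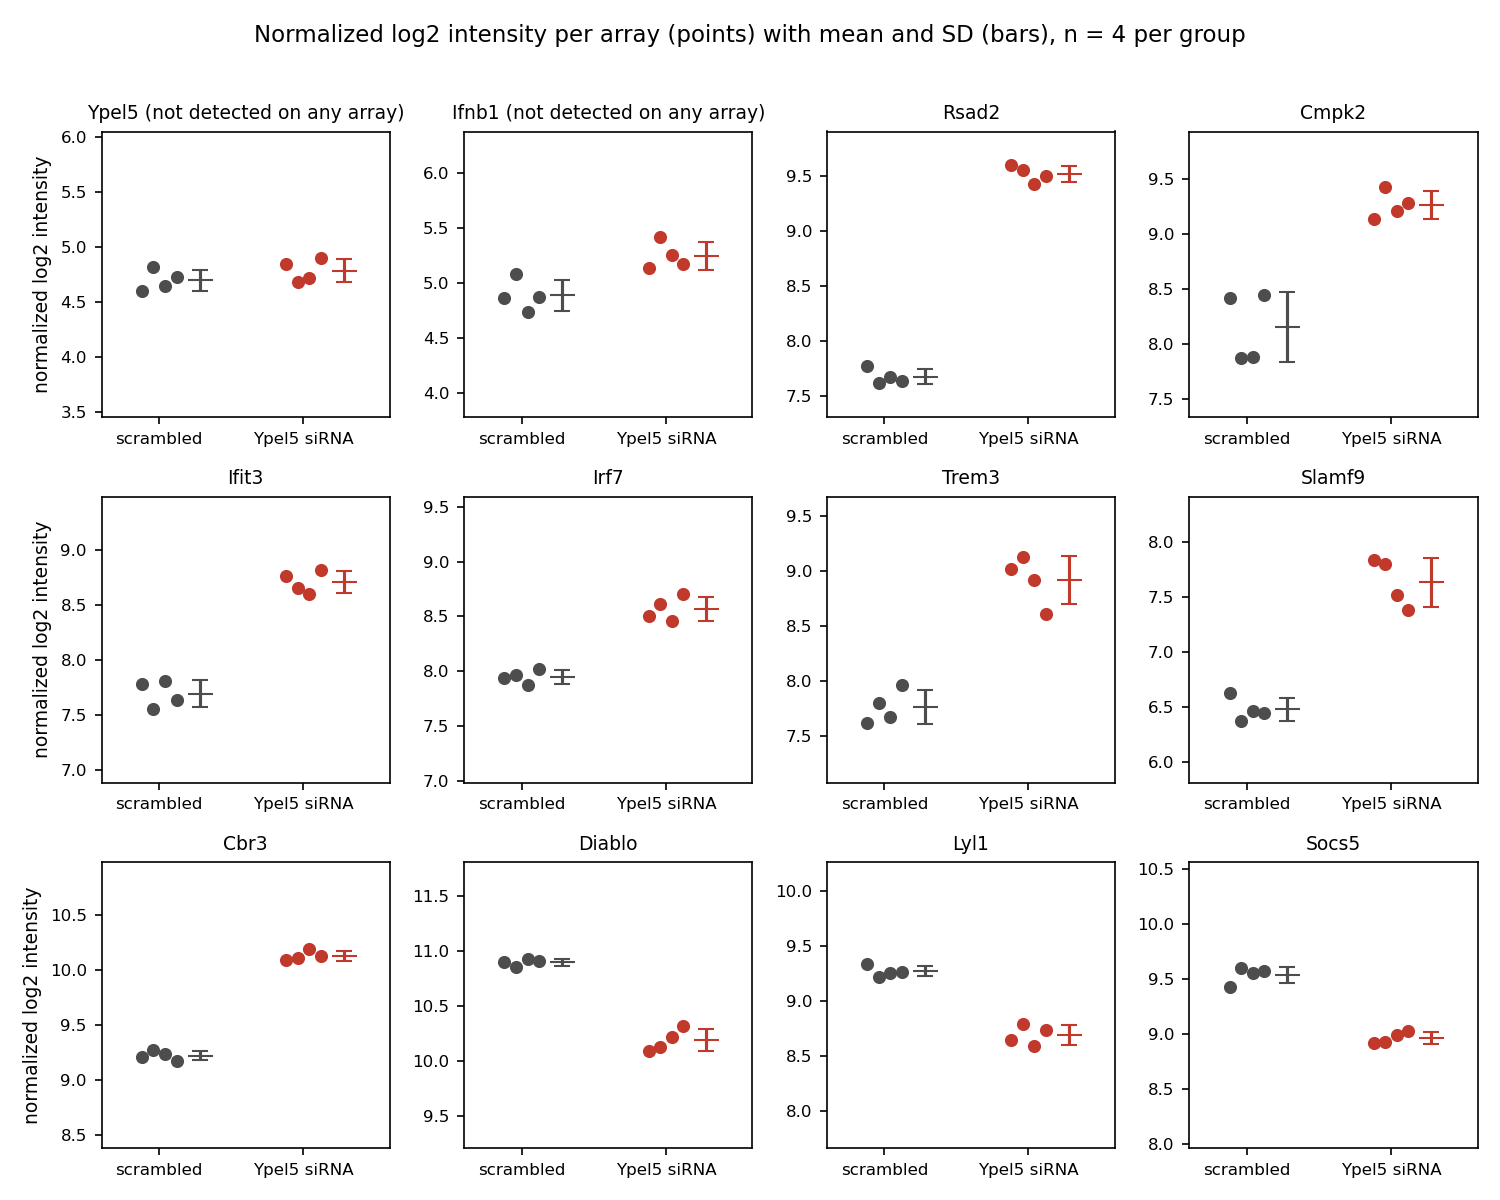
Normalized log2 intensity of 12 genes on each array (points) by siRNA group, with mean and SD (bars, n = 4); every panel spans the same range of log2 units. Ypel5 and Ifnb1 were below background on every array, and Rsad2 had means of 7.67 in the scrambled group and 9.52 in the Ypel5 siRNA group.

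Across 8145 genes tested, 404 (4.96%) passed a limma adjusted p of 0.05, of which 241 were higher and 163 lower after the Ypel5 siRNA. Most changes were small, with a median of 1.34-fold among genes that were higher and 1.26-fold among those that were lower. At least 1.5-fold changes were seen for 70 of them (62 higher, 8 lower) and at least 2-fold changes for 11 higher and 0 lower genes, with the bound in place of the fold for 7 genes below background in the scrambled group. The 4 arrays of one group lay outside the range of the other for 1240 genes, or 15.2% against 2.86% by chance. All 404 called genes were among them, but a call itself favours such genes, so this is no separate support for the calls. The first principal component held 27.9% of the variance and separated the groups, with scores from -9.42 to -7.90 for scrambled and from 7.57 to 10.2 for Ypel5 siRNA arrays. With background correction and only a common median per array, 235 genes passed, 205 higher and 30 lower, so that the share of higher genes was 87.2% in place of 59.7%, while the median change of all genes was log2 0.0366 in place of 0.0008. Leaving out any 1 of the 8 arrays lowered the count of 404 to between 187 and 269. Of the 49 called genes followed through the alternatives, 21 passed in every alternative that gave them a value. Among these, Pdlim4 and ENSMUSG00000053338 had values in only 15 alternatives and Slpi and Sirpb1a in 20, against 21 for Rsad2. Without both replicate 1 arrays Ccl2, Ccl5, Cd40, Fas, Tlr4, Tlr2, Slc2a1, Sqstm1 and Chac1 were among the 26 of 47 that did not pass.

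Interferon-stimulated genes rose as a group. Of 33 measured members, 15 rose, 0 fell and 18 did not pass, and 32 of 33 had a change above 0. Adjusted over the list alone, 20 rose and 0 fell. Examples were Rsad2 and Ifit3 above, Irf7, the transcription factor that amplifies interferon production (log2 0.62, SE 0.065, adjusted p = 0.00301), and Parp14 (log2 0.56, SE 0.067, adjusted p = 0.00498). The mean change was log2 0.45, and the camera set test gave an adjusted p of 1.87e-16 with its preset correlation between genes. With an estimated correlation the adjusted p was 0.0585.

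Genes of the TBK1 and IKBKE pathway and of nucleic acid sensing were not shown to move more than other genes (camera adjusted p = 0.305). Of 21 measured members 2 were higher and 0 lower. By fry, which does not compare a list with other genes, they were higher on balance (mean log2 0.06, adjusted p = 0.00438). Adjusted over the list alone, the counts were also 2 and 0. The receptor gene Tlr4 rose by log2 0.39 (SE 0.058, adjusted p = 0.010), and Ddx58, the cytosolic RNA sensor RIG-I and also a member of the interferon-stimulated list, by log2 0.54 (SE 0.12, adjusted p = 0.0465). The call of Ddx58 was lost when any of 7 of the 8 arrays was left out. Changes that did not pass were log2 0.11 (SE 0.057, adjusted p = 0.333) for Tbk1, log2 0.13 (SE 0.14, adjusted p = 0.653) for Ikbke and log2 -0.07 (SE 0.048, adjusted p = 0.425) for Irf3. Traf6 was at log2 -0.20 (adjusted p = 0.139), and Ticam1 was at log2 -0.46 (adjusted p = 0.250). Without scrambled replicate 1 or 2 another Ticam1 probe became the brightest, at log2 0.19 and 0.13, while the first stayed between log2 -0.60 and -0.26 whichever array was left out. Ifnb1, the interferon-beta gene, was detected on 0 of the 8 arrays, with log2 readings of 4.89 ± 0.14 in the scrambled and 5.25 ± 0.13 in the Ypel5 siRNA group (SD, n = 4 each, two-sided exact permutation p = 0.0286, the smallest possible). Its limma adjusted p over all probes was 0.177.

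Inflammatory genes driven by NF-kB were higher as a group (21 measured, 3 rose, 0 fell, mean log2 0.19, camera adjusted p = 0.00343, and adjusted p = 0.0601 with an estimated correlation). The genes that rose were the chemokine genes Ccl2 (log2 0.69, SE 0.097, adjusted p = 0.00874) and Ccl5 (log2 0.68, adjusted p = 0.0148) and the receptor gene Cd40 (log2 0.70, adjusted p = 0.00941), all of which interferons are also known to induce. Without background correction the list's mean was log2 0.09, with Ccl2 at log2 0.40, Ccl5 at 0.23 and Cd40 at 0.28, and the list and these genes still passed. Adjusted over the list alone, 4 rose. Tnf was at log2 -0.19 (SE 0.071, adjusted p = 0.163), Traf1 at log2 0.31 (adjusted p = 0.0562) and the interferon-stimulated chemokine gene Cxcl10 at log2 0.16 (SE 0.091, adjusted p = 0.356). Il6 was detected on 0 of the 8 arrays.

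Of 20 measured oxidative stress genes, 6 rose, 0 fell and 14 did not pass (7 and 0 adjusted over the list alone), with 5 below 0. The mean was log2 0.18 (camera adjusted p = 0.000261, and adjusted p = 0.0585 with an estimated correlation). The carbonyl reductase gene Cbr3 rose by log2 0.91, from 9.22 ± 0.042 to 10.13 ± 0.046 (SD, n = 4 each, adjusted p = 0.000110). Gclm, a subunit of the enzyme that makes the glutathione precursor, rose by log2 0.47 (SE 0.053, adjusted p = 0.00402), Sqstm1 by log2 0.34 (adjusted p = 0.00820) and the biliverdin reductase gene Blvrb by log2 0.33 (adjusted p = 0.0157, and 0.0504 without scrambled replicate 2).

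Of 22 measured glycolysis and hypoxia genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone), with a mean of log2 0.15 and a camera adjusted p of 0.00343. The list's adjusted p was 0.0585 with an estimated correlation and 0.378 with only a common median per array. The genes that rose were Ndrg1 (log2 0.61, SE 0.065, adjusted p = 0.00336), the glucose transporter gene Slc2a1 (log2 0.38, adjusted p = 0.00888), Ankrd37 (log2 0.40, adjusted p = 0.0294) and the phosphofructokinase gene Pfkl (log2 0.21, adjusted p = 0.0344). The call of Ankrd37 was lost when any of 7 of the 8 arrays was left out, and that of Pfkl when any of the 8 was.

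Among macrophage identity genes, 2 of 21 measured rose and 0 fell (3 and 0 adjusted over the list alone). These were the Fc receptor gene Fcgr3 (log2 0.87, SE 0.090, adjusted p = 0.00294) and the receptor gene Tlr2 (log2 0.33, SE 0.048, adjusted p = 0.00914), while Fcgr1 was at log2 0.23 (adjusted p = 0.0633) and Trem2 at log2 0.14 (adjusted p = 0.231). The mean was log2 0.13 (camera adjusted p = 0.0136, and adjusted p = 0.0646 with an estimated correlation). The list's call was lost with only a common median per array (adjusted p = 0.288) and without scrambled replicate 4 (adjusted p = 0.0502).

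Oxidative phosphorylation genes were the only list that camera called lower. Of 37 measured members, 0 passed the limma threshold in either direction, 0 did so adjusted over the list alone, and 6 were lower at an unadjusted p under 0.05. The mean was log2 -0.08 with 30 of 37 members below 0, and the camera adjusted p was 0.00259. With an estimated correlation the adjusted p was 0.0585. The members with the smallest p were the ATP synthase genes Atp5d (log2 -0.23, adjusted p = 0.0727), Atp5c1 (log2 -0.18, adjusted p = 0.101) and Atp5j (log2 -0.13, adjusted p = 0.108). The complex I gene Ndufb7 came next (log2 -0.28, adjusted p = 0.12). Over 21 alternatives, some of them with nearly the same values, Atp5d passed in 5, Atp5c1 and Ndufb7 in 4 each and Atp5j in 1.

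**Figure D2:**
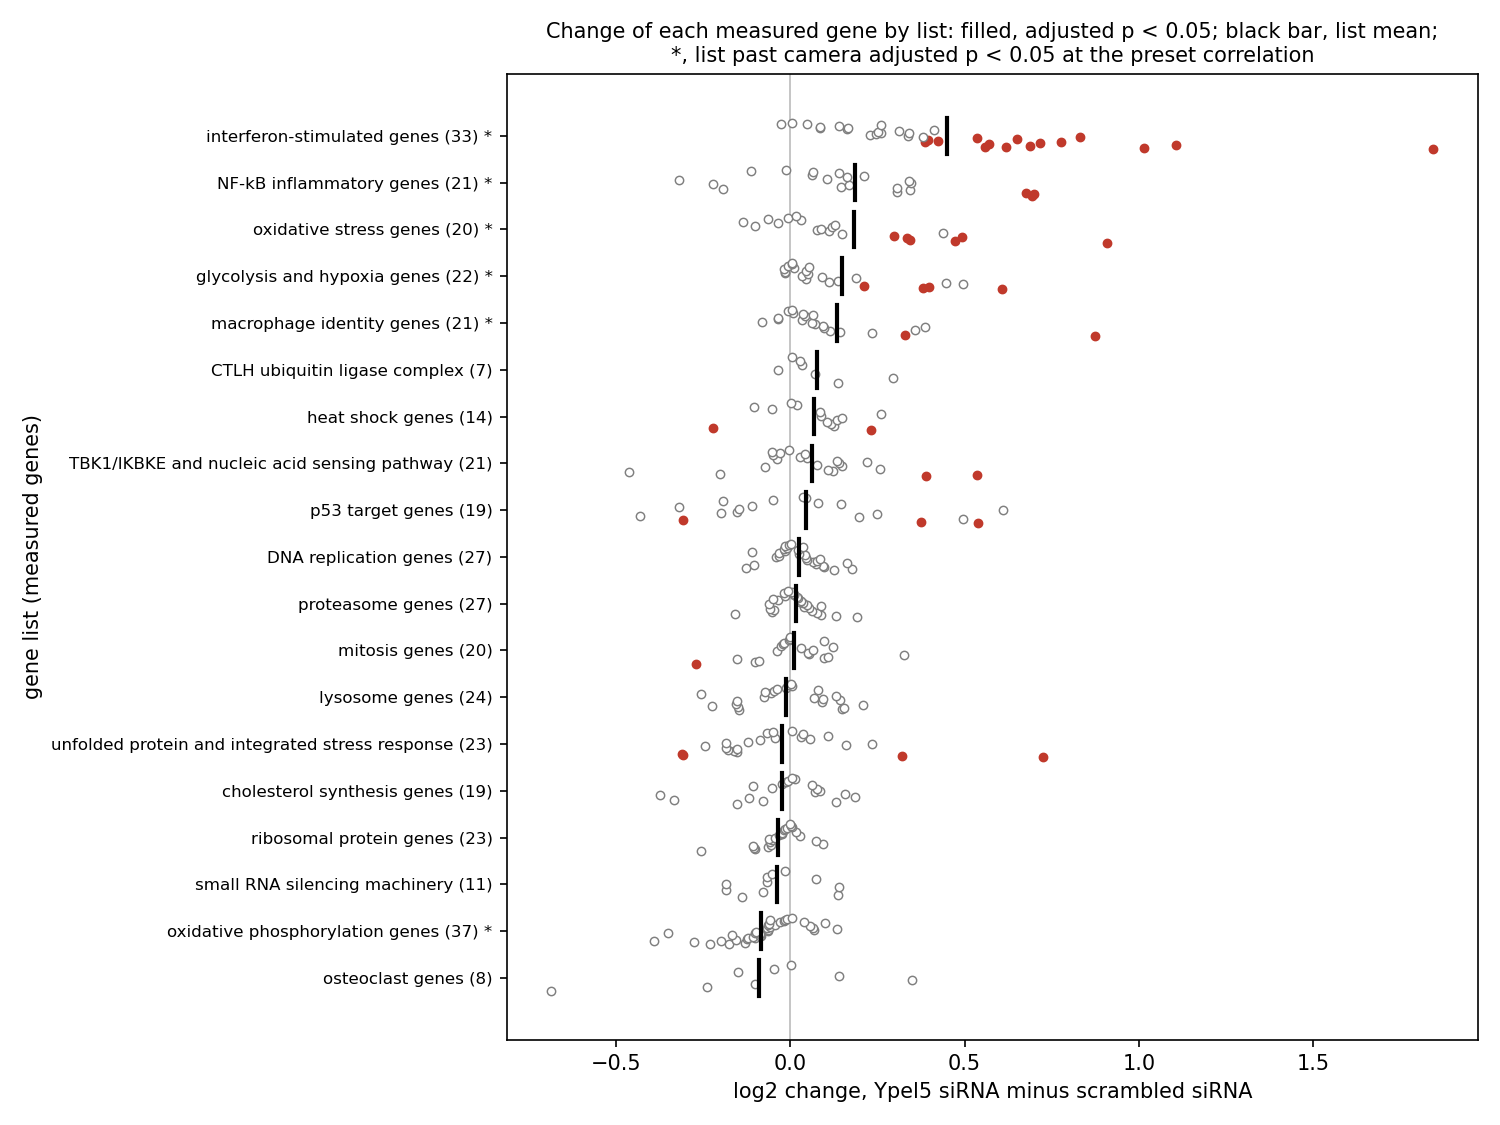
Log2 change (Ypel5 siRNA minus scrambled siRNA) of each measured gene in the 19 gene lists tested, with filled points for limma adjusted p under 0.05, black bars for list means and asterisks for lists past a camera adjusted p of 0.05. The interferon-stimulated genes had the highest mean, log2 0.45, and the 15 members that passed all lay to the right of 0.

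Stress genes moved in both directions. Of 19 measured p53 target genes, Fas (log2 0.54, adjusted p = 0.0148) and Bbc3 (log2 0.38, adjusted p = 0.0207), which encode a death receptor and a pro-apoptotic protein, rose and Ei24 fell by 0.31 (adjusted p = 0.0484), while Ddit4 was at log2 0.49 (adjusted p = 0.0657). Adjusted over the list alone, 4 rose and 2 fell, and the camera adjusted p was 0.779. Of 23 genes of the unfolded protein and integrated stress responses, Trib3 (log2 0.72, SE 0.083, adjusted p = 0.00419) and Chac1 (log2 0.32, adjusted p = 0.0148), targets of the integrated stress response, rose, and the endoplasmic reticulum genes Creld2 and Dnajc3 fell by 0.31 each (adjusted p = 0.0366 and 0.0400). The counts adjusted over the list alone were the same, and the camera adjusted p was 0.252. The calls of Ei24 (any of the 8 arrays), Creld2 and Dnajc3 (7 of the 8 each) and Bbc3 (Ypel5 siRNA replicate 1 or scrambled replicate 3) were lost when 1 array was left out, with adjusted p of up to 0.115.

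The CTLH ubiquitin ligase complex, to which human YPEL5 is known to bind, had 0 of 7 measured members past the limma threshold, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05. Its camera adjusted p was 0.334. Rmnd5b was at log2 0.29 (adjusted p = 0.184), Ranbp10 at log2 0.14 (adjusted p = 0.134), Ranbp9 at log2 0.07 (adjusted p = 0.570) and Mkln1 at log2 -0.04 (adjusted p = 0.743), and Wdr26 was detected on 1 of the 8 arrays. Of the other Ypel family genes, Ypel1, Ypel2 and Ypel4 were detected on 0 arrays, and Ypel3 rose by log2 0.60 (SE 0.086, adjusted p = 0.00874). As the single measured member it also passed adjusted over the list alone. The rise came from the brighter of its probes, and the dimmer probe differed by log2 -0.01 (SE 0.18). With the mean of the probes the adjusted p of Ypel3 was 0.166.

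The remaining lists did not pass the camera test. Heat shock genes (14 measured) had an adjusted p of 0.159 (0.00138 by fry, higher), with Dnajb1 higher (log2 0.23) and Fkbp4 lower (log2 -0.22). Mitosis genes (20 measured) had an adjusted p of 0.779, with Kif23 lower (log2 -0.27), and their mean of log2 0.011 was above 0 while the median and the test pointed down. Dnajb1, Fkbp4 and Kif23 were named after their values were seen, and adjusted over the list alone they were the same calls. In the lists for DNA replication (27 measured, camera adjusted p = 0.442), cholesterol synthesis (19, 0.831), lysosome (24, 0.831), osteoclast (8, 0.345), ribosomal protein (23, 0.192), proteasome (27, 0.545) and small RNA silencing genes (11, 0.450), 0 genes passed limma, over all genes or adjusted over the list alone. Ribosomal protein genes (mean log2 -0.04) were lower by fry (adjusted p = 0.00133), and by camera with only a common median per array (mean log2 -0.15, adjusted p = 1.23e-09). At an unadjusted p under 0.05 the lists for DNA replication to small RNA silencing held 3, 2, 6, 2, 2, 1 and 1 genes in that order.

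Markers of other cell types were mostly below background. Kept as measured were 0 of 10 fibroblast markers on the array, 1 of 10 lymphocyte markers (Lck), 2 of 6 epithelial markers (Cdh1 and Cldn7) and 1 of 10 dendritic cell and granulocyte markers (S100a8). None of these 4 measured genes passed limma over all genes or at an unadjusted p under 0.05.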

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

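No test in this part was chosen after results were seen. In 142 groups of 4 values (the named genes and 3 measures of each array, per siRNA group), 5 held 1 array far from the other 3, where chance gives about 1 in 20 groups, or 7.1. Slc2a1 read log2 12.51 on scrambled replicate 3 against 12.34 to 12.37 on the other scrambled arrays. Bbc3 read log2 8.96 on scrambled replicate 4 against 9.08 to 9.10. Rrm2b read log2 8.72 on scrambled replicate 1 against 8.91 to 8.92. On Ypel5 siRNA replicate 4, Atp5c1 read log2 13.68 against 13.79 to 13.80 on the other Ypel5 siRNA arrays, and Ehmt1 read log2 5.59 against 5.76 to 5.80.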

How the results depend on the processing

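Leaving out both arrays of replicate 1, the interferon-stimulated list's mean as a result of its own, the count of calls lost, the fold counts with bounds and the check of probes were chosen after results were seen. None of the 49 called genes run under the alternatives turned its direction. Of these, 21 passed in every alternative that gave them a value. With the replicate block 20 did not pass, and without both arrays of replicate 1, 26 of 47 did not. The called genes named after their values were seen were not run. Counts are given as total, higher and lower, against 404, 241 and 163. The source-name number as a block, which is unevenly spread over the siRNA groups and so partly confounded with them, gave 140, 103 and 37. The replicate number as a replicate block gave 107, 79 and 28 (100 of them shared). No label ties same-numbered arrays to a culture: their deviations correlated at 0.038, -0.0034, -0.00077 and 0.18, and 3 of 8 arrays correlated best with their own number, though both arrays of replicate 4 stood apart on the second principal component (10.6 and 11.1). Quantile normalization without background correction, the authors' table and the series' value table gave 671, 380 and 291 each (381 of the 404 shared with the authors' table). A common median only gave 235 and 30 lower, no detection filter 144, 111 and 33, trend and robust variance 774, 432 and 342 (367 shared), and at least 1.5-fold 74, 66 and 8 (70, 62 and 8 with bounds for genes below background in 1 group). Without scrambled replicate 1, 2, 3 or 4 the total was 220, 187, 200 or 269, without Ypel5 siRNA replicate 1, 2, 3 or 4 it was 205, 198, 255 or 267, and without both arrays of replicate 1 it was 68. Over these omissions 56 to 175 were higher and 12 to 100 lower, and fewer arrays give less power. Offset 50 (462), stricter detection (534), the mean of probes (384) and array weights (439) stayed within 1.5 times. The interferon-stimulated list passed in 22 of 23 alternatives, with means from log2 0.31 to 0.50; with an estimated correlation its mean stayed log2 0.4485 but adjusted p was 0.0585, and 0 lists passed, 6 at an unadjusted p under 0.05 and 9 by fry. Values that turned sign, none of them called, were Mkln1 (log2 0.000659 with the source-name block), cholesterol synthesis (0.0177), proteasome (-0.00828) and small RNA silencing genes (0.0284) with a common median (where the median of all genes was 0.0366, above the first and last of these), cholesterol synthesis (0.0134) with stricter detection, and without a filter mitosis (-0.000240) and lysosome genes (0.00355). Over omitted arrays Ticam1 ranged from -0.60 to 0.19, the positive values being those of another probe, mitosis genes from -0.0121 to 0.0321 and lysosome genes from -0.0212 to 0.0172. Where no cause is given, the cause was not tested. Probes below background, Ypel5 and Ifnb1 among them, have no measurable fold; Ypel5 was not run with other filters or with the mean of probes.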

Other observations

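The genes of the next paragraph, the gene families by symbol with their scalings, and the explanations weighed for each pattern were chosen after the results were seen; the predictions for these explanations were written before their tests were run, except that for the siRNA duplex.

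Several genes outside the fixed lists also rose. Receptor genes of myeloid cells among them were Clec4n (log2 0.79, SE 0.080, limma adjusted p = 0.00290), Tlr13 (log2 0.71, SE 0.069, adjusted p = 0.00256), Fcgr4 (log2 0.66, SE 0.077, adjusted p = 0.00438) and Tlr1 (log2 0.39, SE 0.049, adjusted p = 0.00539). As a group by symbol the 12 measured Clec genes did not pass (camera adjusted p = 0.279). Slc40a1, the iron exporter ferroportin, rose by log2 0.70 (SE 0.066, adjusted p = 0.00247), and the glutathione transferase genes Gstm1 by log2 0.48 (adjusted p = 0.0124) and Gsta3 by at least 1.32-fold, its probe being below background on every scrambled array (adjusted p = 0.00912). Ifngr2, a subunit of the interferon-gamma receptor, fell by 0.38 (SE 0.062, adjusted p = 0.0145). These genes were not tested together.

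Chance assignment of arrays to groups was weighed for the count of genes, and for that of gene lists at the preset correlation. Of the 35 splits of the 8 arrays into 4 and 4, only the real one (1 of 35) gave as many as 404 genes, and the highest other gave 1. For gene lists the real split gave 6, the highest other 3, and again 1 of 35 splits gave as many. A share of 1 of 35 is the smallest these splits can give, and every other split mixes arrays of both groups. Such counts are therefore unlikely by chance among these arrays but chance is not excluded. If the replicates are technical, the splits say nothing about chance between cultures. With an estimated correlation the real split and every other gave 0 lists, so the list count is not separated from chance there.

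The rise of the interferon-stimulated genes and the higher readings of the undetected Ifnb1 probe were weighed against a brighter background on the Ypel5 siRNA arrays. At most 0.01% of 10000 random lists matched on brightness, the smallest share they can give, had a mean change as high. The random lists ignore correlation between genes, estimated at 0.213 for the interferon-stimulated list, so their spread is too narrow for it. Of the 12267 probes detected on no array, 0.130% had all 4 Ypel5 siRNA arrays above all 4 scrambled arrays by as much as Ifnb1. Both shares come from background-corrected and quantile-normalized values, in which a background shared by the probes of an array is largely removed. The median difference of these undetected probes was log2 -0.0024. The shares therefore cannot decide whether such a background played a part. Background correction by the detection p-values was tested too: without background subtraction the list's mean change was log2 0.3078 and the list passed. A hypothesis is that the Ypel5 siRNA raised interferon-beta slightly and its target genes with it, but Ifnb1 lay below background and missed the threshold (adjusted p = 0.177). An effect of the siRNA duplex itself and not the loss of Ypel5 cannot be told apart from it. The Ypel5 probe was detected on 0 arrays, and the labels do not say whether a group received more than 1 siRNA sequence.

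The lower oxidative phosphorylation genes are mostly bright, so a loss of linearity among bright probes was weighed. At most 0.01% of 10000 random lists of the same brightness, the smallest share they can give, had a mean change as low as log2 -0.08. The values were quantile normalized, which largely removes shifts shared by genes of equal brightness. The share compares the list with genes of equal brightness after that step. It therefore cannot decide whether a loss of linearity played a part. Random lists ignore correlation between genes. With an estimated correlation camera's adjusted p for the list was 0.0585. The estimate was -0.014, below the preset 0.01, so stronger correlation among its genes does not account for the higher adjusted p. A small biological shift after the siRNA is a hypothesis and was not tested further.

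Genes with a symbol beginning Zfp, mostly zinc finger proteins, were lower as a family, the only one of 109 families to pass (camera adjusted p = 0.0132). With the correlation estimated, at 0.0016, camera's adjusted p was 0.181. The mean of the 148 genes was log2 -0.09, with 107 below 0. Of the 148 genes 7 fell, among them Zfp871, Zfp60 (log2 -0.52) and Zfp420 (log2 -0.37). The 1 that rose, Zfp36l1 (log2 0.45), is of another protein class. At most 0.01% of 10000 random lists of the same brightness had a mean as low, the smallest share they can give. The values were quantile normalized, which largely removes shifts shared by genes of equal brightness. This share therefore cannot decide whether dimness accounts for the fall. The family had the lowest p of the 109 in these same data, and random lists ignore correlation between genes. The share is thus no separate evidence of a fall of the family. The family also passed with quantile normalization without background correction (106 below 0, adjusted p = 0.0422) and in the authors' table (105, 0.0424), but not with only a common median per array (mean log2 -0.03, 84 below 0, adjusted p = 0.0837), which moved the median of all genes to log2 0.0366 and so accounts for part of the smaller mean. Whether the fall is biological was not tested.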
